A study of Triticum aestivum with 24 samples.

How the data were processed

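RNA of wheat flag leaves was measured on the Affymetrix wheat array, 1 sample per array, in 24 samples: the cultivars TAM 111 and TAM 112, at heading and at grain filling, under wet and dry conditions in a greenhouse, with 3 replicates in each of the 8 groups. Total RNA was taken with Trizol and labelled with biotin, per the labels. The deposited values are intensity values, 1 MAS5 signal per probe set and array on the linear scale, scaled by the authors to a common target per the submitters' processing notes (MAS5 version not given in the sources used here). The mean signal after trimming 2% from each end was 500.1 on every array. No array column was unmapped (0) and none duplicated another (0).

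The 61290 probe sets included 111 control probe sets with the AFFX prefix, which were kept out of the main tests. Of the other 61179, those with a signal above 69.0 (the median of all values) in at least 3 arrays were tested, 37516 in all (61.3%). From 47.5% to 52.3% of probe sets lay above that level on each array. Signals were put on the log2 scale after adding 11.71, the 20th percentile of all values. The number of arrays limits the precision of every comparison.

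A linear model with a mean for each of the 8 groups was fitted with limma 3.58.1 in R 4.3.3, with variances moderated by eBayes with a trend (16 residual and 5.53 prior degrees of freedom). A change was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested probe sets. The comparisons were dry against wet in each cultivar and stage, the difference of these changes between cultivars and between stages, TAM 112 against TAM 111 at each stage and grain filling against heading in each cultivar, the last ones averaged over water. Errors of log2 changes are standard errors from limma, and levels are means with SD of 3 arrays. The groups, the comparisons, the rule for naming genes and most alternatives were fixed before the data were examined.

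The fit was tested on simulated data with the group means and residual spread of these arrays. In them the water effect in TAM 112 at grain filling was taken out, and 200 of 37516 probe sets were changed instead. The fit recovered 56% of 100 changes of 2-fold and 87% of 100 of 4-fold, with 153 calls, 10 of them false and 0 in the wrong direction. In the real comparison 31.6% of probe sets were called, so these rates need not hold for it. The list test called a shifted simulated list and did not call an unshifted one. The simulated noise was independent between probe sets, so this check cannot tell how the list test behaves where genes vary together.

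Gene names came from a table that paired 1273 probe sets with 771 genes and left 59906 probe sets without a gene, and 770 of the genes were found in the annotation of the IWGSC CS RefSeq v2.1 assembly. A gene counted as named if its symbol was more than a locus number or it had a synonym, which held for 102 genes (200 probe sets), 78 of them tested (133 probe sets). Where a gene had several probe sets, lists used the brightest, and the rule below used any that passed. Named in the text are, for each water, cultivar and stage effect, up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean above the median of all values, the 5 with the smallest p for each difference of changes, and 2 list members. The largest changes of probe sets without a named gene are given for those with a mean above the same median. These folds are given with the main pseudocount only, which limits them where a group lies near background. Most tested probe sets have no named gene, so the largest changes are likely to fall among them. Other named genes were added after their values were seen.

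Of 22 gene lists fixed beforehand, 13 matched no named gene and 0 had 5 tested genes. Because of this, 12 lists were drawn from the gene names before any groups were compared, 9 of which had the 5 tested genes needed for the list test. They cover LEA proteins and dehydrins, photosynthesis, fructan and starch, redox and detoxification, defence, grain storage proteins, pollen, histones and HMG protein, tubulins, translation, gibberellin 20-oxidases and methyl group metabolism. Lists were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, with p adjusted over 72 tests.

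Alternatives were a pseudocount of 1 or 4 times as large, quantile normalization over all arrays, no filter, a filter at 385.6 (the 75th percentile, 18122 probe sets), a fit of only the arrays compared, array weights, the replicate number as a block, no variance trend and leaving out each array in turn. Leaving out 3 TAM 111 arrays that lay between the cultivars, or all 4 arrays numbered 2 of TAM 111, was chosen after seeing the data. The group labels were also exchanged between arrays in up to 100 splits. Raw intensity files were not used here.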

Results

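Flag leaves of the wheat cultivars TAM 111 and TAM 112 were profiled on 24 Affymetrix wheat arrays, with 3 arrays in each of 8 groups. The groups crossed the cultivar with the developmental stage (heading or grain filling) and the water treatment (wet or dry). The flag leaf is the last leaf formed before the ear and a main source of sugars for the filling grain. The labels name water levels of 90% and 50% of field capacity without tying them to the treatment names, and they were read here as wet and dry, respectively. Each array gave a MAS5 signal for 61290 probe sets, of which 37516 were bright enough to be tested. All arrays had the same trimmed mean signal of 500.1, and their median signals ran from 60.4 to 77.2. Nothing in the labels says that the 3 replicates of a group were separate plants, so the p-values measure the spread between these samples, which may be technical.

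Arrays of one group correlated at 0.951 to 0.971 (Pearson, across probe sets on the log2 scale, median 0.964), against 0.864 to 0.962 (median 0.932) for arrays of different groups. The first principal component carried 27.5% of the variance and the second, which separated the cultivars, 14.8%. On the second component TAM 112 arrays lay between -51.4 and -29.5 and most TAM 111 arrays between 45.2 and 62, but replicate 2 of TAM 111 lay in between in 3 groups, at 1.71 (heading, wet), 10.5 (heading, dry) and 4.05 (grain filling, wet). Replicate 2 of TAM 111 at grain filling under dry conditions lay with its cultivar, at 61.2. The 3 intermediate arrays were kept, and counts without them are given wherever these differ by more than 1.5 times. The log2 ratio of the 3' to the 5' actin probe set, a measure of RNA integrity, was 0.12 ± 0.264 (SD, n = 3) in wet and 1.76 ± 0.629 in dry TAM 111 leaves at heading. It was 0.612 ± 0.94 and 0.793 ± 1.34 in TAM 112. At grain filling it was 1.5 ± 1.26 and 2.2 ± 2.18 in TAM 111 and 1.2 ± 0.505 and 1.11 ± 1.96 in TAM 112. The same ratio for GAPDH went from -2.43 ± 0.478 in wet to -1.7 ± 0.735 in dry TAM 111 leaves at grain filling and from -2.73 ± 1.25 to -1.06 ± 0.489 in TAM 112. At heading it went from -1.44 ± 0.748 to -1.34 ± 0.75 and from -0.939 ± 0.41 to -1.14 ± 0.356. The GAPDH ratio was negative on every array, the 3' probe set being the dimmer one, which limits it as a measure of RNA integrity. The ratio for EF1a had group means from -2.31 to 0.825, with an SD of up to 3.82.

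**Figure D1:**
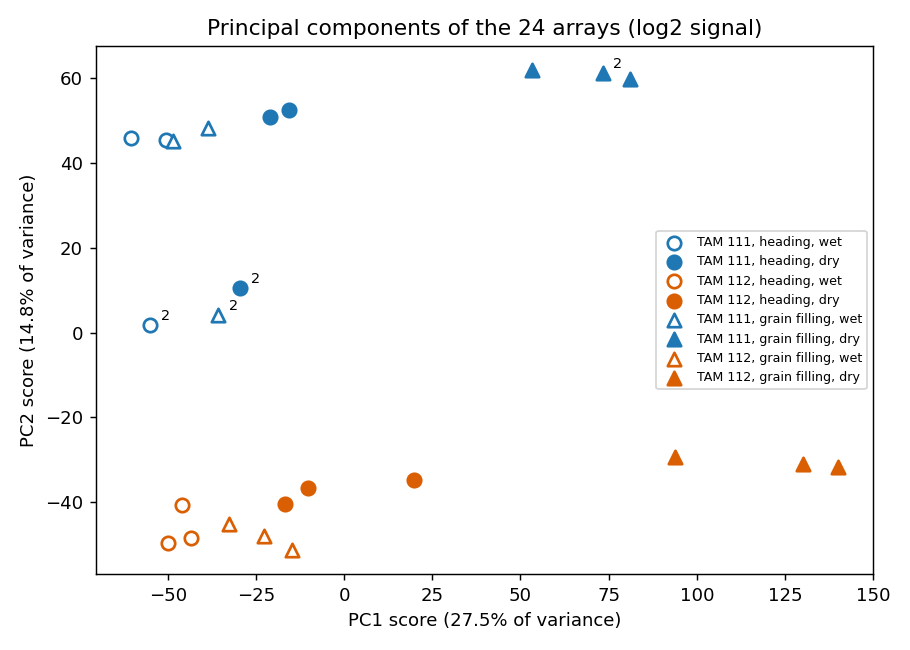
Positions of the 24 arrays on the first (27.5% of variance) and second (14.8%) principal components of the log2 signals, with one point per array, circles for heading, triangles for grain filling, filled symbols for dry and open symbols for wet. Replicate 2 of TAM 111, marked 2, lies between the cultivars at 1.71, 10.5 and 4.05 on the second component in 3 of its 4 groups.

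At heading, dry TAM 111 leaves carried more transcript of 6-FEH, lgul and SAHH and much less of the pathogenesis-related gene PR5. The fructan exohydrolase 6-FEH, which frees fructose from stored fructan, rose 2.66-fold, from a signal of 517.3 ± 138 to 1373 ± 197 (SD, n = 3; limma, log2 change 1.41, SE 0.261, adjusted p = 0.00204). The glyoxalase gene lgul rose 1.96-fold (adjusted p = 0.00308), and SAHH, which recycles the by-product of methylation reactions, rose 1.69-fold (adjusted p = 0.00147). PR5, a thaumatin-like defence protein, fell 6.41-fold, from 8746 ± 4020 to 1305 ± 373 (adjusted p = 2.57e-04). In all, 1705 probe sets passed in limma (4.54% of those tested), 644 higher and 1061 lower in dry leaves, and 780 of them changed by at least 2-fold. For 6 of the 7 genes taken by the naming rule, all 3 dry arrays lay beyond all 3 wet arrays, the exception being a probe set for rbcl, the plastid gene of the large Rubisco subunit. Chance gives such a separation for 10% of genes, but these genes were chosen for their change on the same arrays. The actin ratio also differed between these wet and dry arrays (0.12 ± 0.264 against 1.76 ± 0.629, SD, n = 3).

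The weaker falls in TAM 111 at heading lost their calls with 1 array fewer. The zinc finger gene WZF1 fell 2.58-fold (log2 change -1.37, adjusted p = 0.03), and without any 1 of the 6 arrays it gave -1.17 to -1.48 with adjusted p between 0.0519 and 0.126. COMT1, a methyltransferase of lignin synthesis, fell 1.53-fold (adjusted p = 0.0241). Its call was lost without wet replicate 3 (log2 change -0.44, adjusted p = 0.14), dry replicate 1 (-0.62, 0.0733) or dry replicate 2 (-0.51, 0.106), against -0.61 with all. The rbcl probe set fell 3.23-fold (adjusted p = 0.0498). That call was lost without wet replicate 2 (-1.60, 0.159), wet replicate 3 (-1.07, 0.251), dry replicate 1 (-1.42, 0.205) or dry replicate 3 (-1.59, 0.177), against -1.69 with all. The brightest rbcl probe set gave a log2 change of -0.15 (adjusted p = 0.656). Without the intermediate arrays all of these calls ended as well, at adjusted p = 0.116 for WZF1, 0.0669 for COMT1 and 0.106 for rbcl. The number of called probe sets dropped to 927 without wet replicate 2, 982 without dry replicate 1, 796 without dry replicate 3 and 857 without both intermediate heading arrays and that of grain filling. It was 758 without the 4 arrays numbered 2 of TAM 111, and it rose to 2595 with array weights. Probe sets without a named gene changed most, up to 14.5-fold higher and 18.7-fold lower.

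In TAM 112 at heading, the dry treatment raised a pair of genes whose products accumulate in drying plant cells. The dehydrin Rab15 rose 9.96-fold, from 55.88 ± 35.5 to 677.8 ± 485 (SD, n = 3; log2 change 3.32, SE 0.465, adjusted p = 2.09e-04; 6.43-fold with a pseudocount 4 times as large), and the late embryogenesis abundant gene LEA1 rose 3.41-fold, from 58.46 ± 19.6 to 279 ± 245 (adjusted p = 0.0403). As in TAM 111, 6-FEH rose (2.14-fold, adjusted p = 0.0191; another, dim probe set did not follow) and SAHH rose (1.56-fold, adjusted p = 0.00811). The rbcl probe set fell 3.43-fold (adjusted p = 0.0438), while the brightest rbcl probe set gave 0.06 (adjusted p = 0.901). For 5 of 5 named genes all dry arrays lay beyond all wet arrays. Limma called 1351 probe sets (622 higher, 729 lower; 631 by at least 2-fold). Those without a named gene changed up to 28.2-fold higher and 29.2-fold lower.

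In TAM 112 at heading the calls of LEA1, 6-FEH, SAHH and the rbcl probe set were lost with 1 array fewer. LEA1 lost its call without wet replicate 1 (adjusted p = 0.0592), wet replicate 2 (0.158), wet replicate 3 (0.107) or dry replicate 1 (0.285), with log2 changes of 1.12 to 1.99 against 1.77. It also lost it with a pseudocount of 1 (0.0661), without the filter (0.0574), without the variance trend (0.0711) or with only these 6 arrays in the fit (0.098). 6-FEH lost it without wet replicate 2 (0.102), dry replicate 1 (0.114) or dry replicate 2 (0.0679). SAHH lost it without wet replicate 1 (0.0551), wet replicate 2 (0.0594) or dry replicate 1 (0.0579). The rbcl probe set lost it without wet replicate 1 (0.0593), wet replicate 2 (0.269), dry replicate 1 (0.13), dry replicate 2 (0.131) or dry replicate 3 (0.0721). The total dropped to 735 without wet replicate 1, 508 without wet replicate 2 and 479 without dry replicate 1.

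The cultivars shared much of the heading response: 687 probe sets were called in both with the same sign (282 higher, 405 lower), where independent lists would share 31.3, and 1 was called with opposite signs. The shared number dropped to 427 without TAM 111 dry replicate 3, 432, 345 and 351 without TAM 112 wet replicate 1, wet replicate 2 and dry replicate 1, and 443 without the 3 intermediate arrays. The difference in response between the cultivars passed for 1 probe set. At an unadjusted p below 0.05 there were 1923 of 37516, close to the share that chance alone would give. It belonged to GA20ox1d, an enzyme of gibberellin synthesis, whose signal went from 20.07 ± 4.22 to 81.37 ± 25.4 in TAM 111 and from 111.1 ± 14.3 to 16.02 ± 8.74 in TAM 112 (SD, n = 3; difference in log2 change -3.71, SE 0.532, adjusted p = 0.0221). On this probe set the water effect passed in each cultivar, 2.88-fold higher in TAM 111 (adjusted p = 0.0203) and 4.55-fold lower in TAM 112 (0.00147). The folds were 3.85 and 7.14 with a pseudocount of 1 and 1.89 and 2.52 with one 4 times as large. The TAM 111 call (log2 change 1.52) ended with a pseudocount of 1 (1.94, adjusted p = 0.0719), with only its 6 arrays in the fit (1.52, 0.0707) and without the 3 intermediate arrays (1.36, 0.188) or the 4 arrays numbered 2 (1.36, 0.211). It also ended without wet replicate 2 (1.57, 0.0569), wet replicate 3 (1.41, 0.0752), dry replicate 2 (1.32, 0.0945) or dry replicate 3 (1.56, 0.0705). The TAM 112 call held without any 1 of its 6 arrays (adjusted p between 0.00182 and 0.0132). The means of 20.07 (TAM 111, wet) and 16.02 (TAM 112, dry) lay far below the filter of 69, not far above the pseudocount. Those of 81.37 and 111.1 lay above the filter. A second GA20ox1d probe set moved the other way (108.9 ± 10.3 to 61.23 ± 42.2 and 77.21 ± 20.3 to 121.9 ± 33.3, difference 1.55, adjusted p = 0.978). The difference of -3.71 was -2.26 with the larger pseudocount, and its call ended with a pseudocount of 1 (-4.78, adjusted p = 0.299), with only the 12 arrays compared (0.21), without the 3 intermediate arrays (0.413) and on leaving out any 1 of the 12 arrays (0.0578 to 0.102) other than TAM 111 dry replicate 1 and TAM 112 dry replicate 3. No probe set passed without TAM 111 wet replicate 1, wet replicate 2, dry replicate 2 or dry replicate 3, nor without TAM 112 wet replicate 2, wet replicate 3, dry replicate 1 or dry replicate 2, and 2 passed without TAM 111 dry replicate 1. The genes called in one cultivar alone were not shown to differ: the difference was 2.15 for PR5 (adjusted p = 0.751), 1.92 for Rab15 (0.862), 1.46 for LEA1 (0.971) and -0.41 for lgul (0.984).

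At grain filling the dry treatment changed far more transcripts, and with the main pseudocount LEA1 had the largest rise of the named genes in both cultivars. In TAM 111, LEA1 rose 19.2-fold, from 64.14 ± 20.3 to 1438 ± 355 (SD, n = 3; log2 change 4.26, SE 0.477, adjusted p = 1.45e-06), and Rab15 rose 4.07-fold, from 81.94 ± 12.9 to 400.3 ± 211 (adjusted p = 0.00321), on the probe set used for it in the other comparisons. A second, dimmer Rab15 probe set rose 7.31-fold (adjusted p = 3.54e-04; 9.97-fold with a pseudocount of 1 and 4.25-fold with one 4 times as large). The small heat shock gene hsp16.9A rose 10.9-fold (adjusted p = 0.001), from a wet signal of 3.046 ± 0.288, below the pseudocount, to 173 ± 125. Its fold is therefore set by the pseudocount (36.7-fold with a pseudocount of 1 and 3.99-fold with one 4 times as large). With a pseudocount of 1 the rise of hsp16.9A was larger than that of LEA1 (22.4-fold). A pair of fructan breakdown genes rose, 6-FEH 2.46-fold (adjusted p = 9.58e-04) and 1-FEH 1.99-fold, from 7722 ± 654 to 15400 ± 1430 (adjusted p = 8.52e-06). The xylanase inhibitor XIP-I rose 2.89-fold (adjusted p = 0.0103, and 0.0893 without the 4 arrays numbered 2 of TAM 111), the protein repair methyltransferase PIMT 2.66-fold (6.40e-05), the phytochelatin synthase TaPCS1 2.58-fold (1.50e-04) and the beta-tubulin tubb1 2.54-fold (2.67e-04).

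PR5 fell 7.77-fold in dry TAM 111 leaves at grain filling, from 5081 ± 3500 to 568.3 ± 168 (SD, n = 3; adjusted p = 1.41e-05), and the rbcl probe set 9.1-fold, from 14580 ± 1000 to 1590 ± 58.3 (adjusted p = 5.91e-05), while the brightest rbcl probe set gave -0.29 (adjusted p = 0.158). The ribosomal protein gene RPS29 fell 2.12-fold (adjusted p = 9.50e-04), the histone gene wcH2B-8 1.79-fold (0.0015), the chromatin protein gene Hmgb3 1.52-fold (4.62e-04) and the tubulin tubb3 1.51-fold (0.00663, and 0.168 without the 4 arrays numbered 2). A second RPS29 probe set, the brighter one, gave -0.30 (adjusted p = 0.797). For 16 of 16 named genes all dry arrays lay beyond all wet arrays. Limma called 7096 probe sets (18.9%), 3496 higher and 3600 lower, 2856 of them by at least 2-fold; without the 4 arrays numbered 2 of TAM 111, an alternative chosen after seeing the data, the number was 3867. Probe sets without a named gene changed most, up to 195-fold higher and 89.1-fold lower.

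In TAM 112 at grain filling, LEA1 rose 93.4-fold, from 24.3 ± 20.8 to 3117 ± 1030 (SD, n = 3; log2 change 6.55, SE 0.477, adjusted p = 2.61e-09). The wet signals lay under the filter of 69, so the size of this fold depends on the pseudocount (153-fold with a pseudocount of 1 and 44-fold with one 4 times as large). XIP-I rose 10.1-fold, from 82.36 ± 30.5 to 900.3 ± 75.3 (adjusted p = 2.10e-06), hsp16.9A 7.75-fold, from 8.658 ± 8.09 to 159.5 ± 104 (0.0021; 18.4-fold and 3.43-fold with these pseudocounts), and Rab15 7.07-fold (6.64e-05). The fructan genes 6-FEH and 1-FEH rose 2.76-fold (adjusted p = 1.50e-04) and 1.99-fold (4.14e-06), Glc1 2.74-fold (1.74e-05), PIMT 2.8-fold (1.73e-05) and the glutathione transferase GSTZ1 2-fold (1.56e-07). PR5 fell 9.95-fold, from 1062 ± 470 to 96.37 ± 50.8 (adjusted p = 1.65e-06), and the rbcl probe set 9.96-fold (1.81e-05), with -0.32 (adjusted p = 0.0817) at its brightest probe set. The tubulins tubb3 and tubb2 fell 2.54-fold (adjusted p = 5.62e-07) and 2.1-fold (0.00531), wcH2B-8 2.29-fold (1.93e-05) and RPL9 2-fold (2.50e-04). A dim wcH2B-8 probe set went the other way (14.92 ± 14 to 41 ± 3.24). The glycolytic genes Pgk-1 and GAPN fell 2.16-fold (adjusted p = 5.32e-06) and 2.11-fold (1.92e-05). For 16 of 16 named genes all dry arrays lay beyond all wet arrays. Limma called 11869 probe sets (31.6%), 5057 higher and 6812 lower, 4756 by at least 2-fold; with only these 6 arrays in the fit the number was 7794. Probe sets without a named gene changed most, up to 414-fold higher and 126-fold lower.

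**Figure D2:**
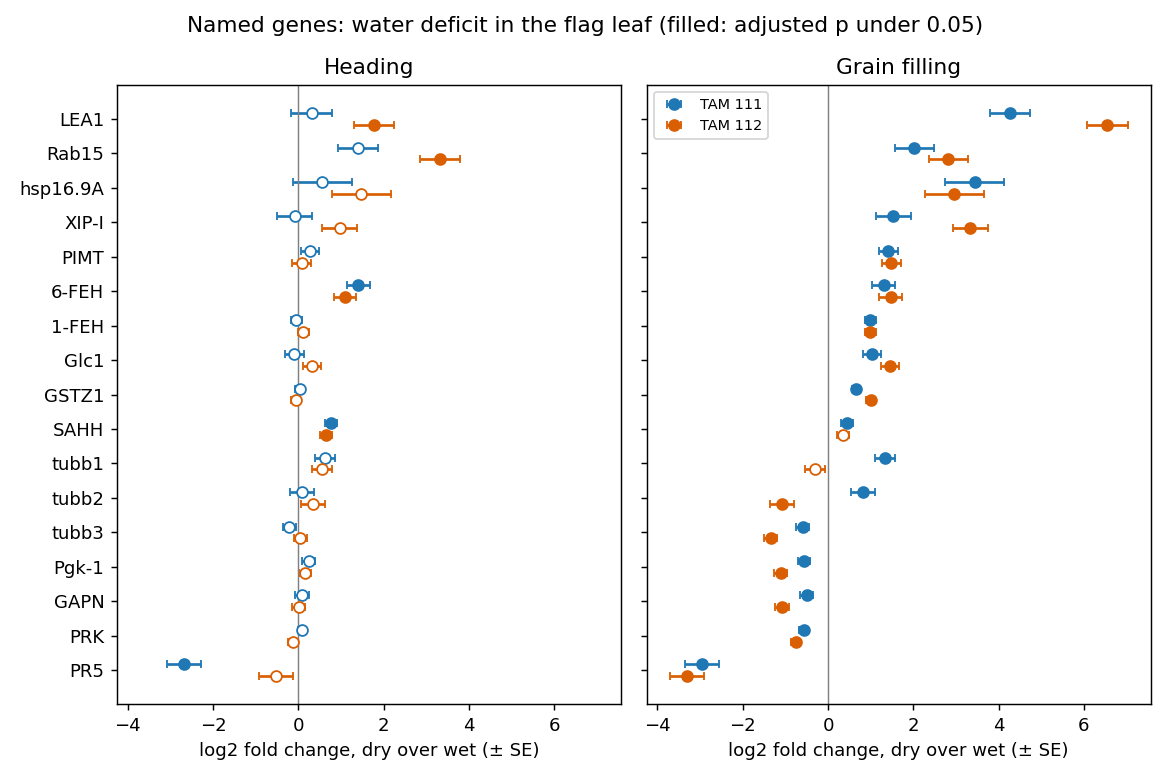
Log2 fold change of dry over wet leaves (x axis, bars are standard errors from limma, n = 3 arrays per group) for 17 named genes (y axis) in TAM 111 and TAM 112, with one panel per stage and filled symbols where the adjusted p was below 0.05. LEA1 reached 4.26 and 6.55 at grain filling, where PR5 lay at -2.96 and -3.32; PRK and Pgk-1 in TAM 111 at grain filling were not called after quantile normalization (adjusted p = 0.21 and 0.079).

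Photosynthesis genes were lower in dry leaves at grain filling as the authors scaled the arrays. Of 7 such genes (petC, PsbP, PsbO, PRK, FBP, rbcl and Trx-M), 4 fell in TAM 111 and 5 in TAM 112, and all 7 passed when adjusted over the list alone, but after quantile normalization only 0 and 3 were called and the signs of petC (0.02) and rbcl (0.07) turned in TAM 111 and that of rbcl (0.03) in TAM 112. Phosphoribulokinase (PRK), a Calvin cycle enzyme, fell 1.48-fold in TAM 111 (adjusted p = 2.95e-04; after quantile normalization -0.20, adjusted p = 0.21). In TAM 112 PRK fell 1.69-fold, from 51230 ± 3120 to 30380 ± 3350 (SD, n = 3; adjusted p = 5.66e-06; after quantile normalization -0.44, adjusted p = 0.0021). FBP, another Calvin cycle enzyme, went from 15650 ± 497 to 12330 ± 354 in TAM 111 (log2 change -0.34, adjusted p = 0.0102) and from 16730 ± 637 to 10020 ± 1710 in TAM 112 (-0.75, adjusted p = 1.98e-06; after quantile normalization -0.69, adjusted p = 7.34e-06). The list test gave adjusted p = 0.0319 in each cultivar with the preset correlation and adjusted p = 0.477 with an estimated correlation, and it lost both calls without the 3 intermediate arrays (0.135 and 0.0704). Quantile normalization ended both (0.693 and 0.361) and called 2 other lists in their place, methyl group metabolism in dry TAM 111 leaves (0.0413) and tubulins between the cultivars at grain filling (0.0413). As deposited, neither list passed (adjusted p = 0.0912 and 0.0519 with the preset correlation, and adjusted p = 0.475 and 0.477 with an estimated correlation). The 200 brightest probe sets shifted in the same way, with 90.5% of them lower in dry TAM 111 leaves at grain filling and 84.5% in TAM 112 as deposited, against 58% and 61% after quantile normalization. Pgk-1 in TAM 111 fell 1.48-fold as deposited (adjusted p = 0.0086) and by 0.40 on the log2 scale after quantile normalization (adjusted p = 0.079).

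Other groups were small. Of 5 tested fructan and starch genes, 2 rose in TAM 111 at grain filling and 4 in TAM 112, where the beta-amylase BMY1 went from 11.6 ± 13.1 to 68.38 ± 28.1 (SD, n = 3; adjusted p = 0.00817), and 1 rose in each cultivar at heading. The list test did not pass at grain filling in TAM 111 (adjusted p = 0.13) or TAM 112 (0.0519), nor with an estimated correlation (adjusted p = 0.475 in both), nor at heading (adjusted p = 0.29 in both). Of 5 genes of methyl group metabolism, PIMT, COMT1 and PEAMT1 rose in TAM 111 at grain filling and PIMT and COMT1 in TAM 112 (4 and 3 genes after quantile normalization), while at heading SAHH rose (0.49 at its brightest probe set, adjusted p = 0.0118) and COMT1 fell in TAM 111. Tubulins split, with 3 of 6 higher and 1 lower in TAM 111 at grain filling (2 higher after quantile normalization) and 3 lower in TAM 112. Of 7 defence genes, XIP-I and Glc1 rose and PR5 fell in both cultivars at grain filling, and PR5 fell in TAM 111 at heading. Of 6 redox and detoxification genes, lgul rose in TAM 111 at heading, TaPCS1 rose in TAM 111 at grain filling, and in TAM 112 at grain filling GSTZ1 rose while lgul and Prx1 fell (1 lower after quantile normalization). GSTZ1 is counted there on its brightest probe set; on the one that rose 2-fold in TAM 112 it also rose in TAM 111 at grain filling (1.57-fold, adjusted p = 6.12e-05). Of 8 translation genes, 1 rose and 1 fell in TAM 111 at grain filling (2 and 0 after quantile normalization) and 2 rose and 2 fell in TAM 112 (3 and 2), and of 5 histone and HMG genes Hmgb3 alone fell in each, the brightest wcH2B-8 probe set not being called. Of 3 gibberellin 20-oxidases tested on the brightest probe set of each, 0 were called for water, while the dimmer GA20ox1d probe set was called in each cultivar at heading, in opposite directions.

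Lists fixed before the data were examined held few named genes on this array. The dehydrin and LEA list had 2 tested genes, LEA1 and Rab15, of which 0 passed in TAM 111 at heading (1 when adjusted over the list alone; Rab15 gave 1.39, adjusted p = 0.0977, and LEA1 0.31, adjusted p = 0.821). Both rose in each of the other 3 water comparisons, also when adjusted over the list alone (1 with a pseudocount of 1 in TAM 112 at heading). The same 2 genes made up the corresponding list drawn from gene names. For sucrose, fructan and starch, 1-FEH was the 1 tested gene, and it rose at grain filling in both cultivars. For heat shock proteins, hsp16.9A rose at grain filling in both, and passed at heading in TAM 112 when adjusted over the list alone (1.48, adjusted p = 0.294 over all). For antioxidant enzymes, the brightest GSTZ1 probe set rose in TAM 112 at grain filling (0.45, adjusted p = 0.00582). Of PsbP and PsbO in the photosystem list, 1 fell in each cultivar at grain filling (0 after quantile normalization, and 2 when adjusted over the list alone). The Calvin cycle list, with rbcl alone, had 0 called. It had 1 with p left unadjusted, since a list of 1 gene leaves nothing to adjust. The peroxidase list, with PER1 alone, had 0 called in limma (log2 change 0.61 in TAM 112 at grain filling, adjusted p = 0.175).

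Marker genes of other tissues were not called. The avenin-like gene avnlb had a mean signal of 6855 over all arrays, while Gli-8 (151.1), WMAI-1 (119.7), LMW-GS (88.89) and the pollen gene raftin1b (44.42) lay near the filter. The fixed list of grain storage proteins had 1 tested gene, which was not called. Of 5 tested grain storage protein and inhibitor genes drawn from gene names, 0 were called by limma in any comparison, and 0 passed in any water comparison when adjusted over the list alone. The 1 tested pollen gene, raftin1b, was not called either (-0.33 and -0.05 at heading, adjusted p = 0.825 and 0.98). Its limma p before adjustment was below 0.05 only between stages in TAM 112 (-0.92), a list of 1 gene leaving p unadjusted. At grain filling the median log2 change of the storage list was -0.33 in TAM 111 and 0.01 in TAM 112, with list test adjusted p = 0.717 and 0.938.

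The overlap between cultivars was larger at grain filling: 5383 probe sets were called in both with the same sign (2653 higher, 2730 lower; 1120 expected of independent lists) and 21 with opposite signs. Without the 4 arrays numbered 2 of TAM 111, 3211 were shared, against 413 at heading. Of the probe sets called in TAM 111, 95.7% had the same sign in TAM 112, and log2 changes over all tested probe sets correlated at 0.715 (Pearson, across probe sets, which are not independent replicates). Of the heading calls, 1168 (68.5%) in TAM 111 and 963 (71.3%) in TAM 112 were called with the same sign at grain filling, several times the number that independent lists would share. The difference in response between the cultivars at grain filling passed for 13 probe sets, none with a named gene, the smallest adjusted p being 3.87e-04. At an unadjusted p below 0.05 there were 5216 of 37516, above the share that chance alone would give, though probe sets are not independent. The tubulins came closest among named genes: tubb1 went from 1850 ± 367 to 4689 ± 786 in TAM 111 and from 2456 ± 715 to 1935 ± 254 in TAM 112 (SD, n = 3; difference -1.65, SE 0.334, adjusted p = 0.0632), and tubb2 from 911.2 ± 161 to 1687 ± 629 and from 1007 ± 244 to 469.3 ± 97.8 (-1.90, SE 0.399, adjusted p = 0.0668). For LEA1 the difference was 2.28 (adjusted p = 0.149), for XIP-I 1.80 (0.174) and for TaPCS1 -0.91 (0.208). The count of 13 rose to 26 without TAM 111 dry replicate 1, 76 without TAM 112 wet replicate 1 and 2438 without TAM 112 dry replicate 3, and dropped to 3 without TAM 111 dry replicate 3, 3 without TAM 112 dry replicate 1 and 2 without TAM 112 dry replicate 2. With array weights it was 1552, without the 3 intermediate arrays 24 and without the 4 arrays numbered 2 of TAM 111 20. With the replicate number as a block the count was 167, with the larger pseudocount 37 and after quantile normalization 23. Without the variance trend 8 passed, and with only the arrays compared 4.

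**Figure D3:**
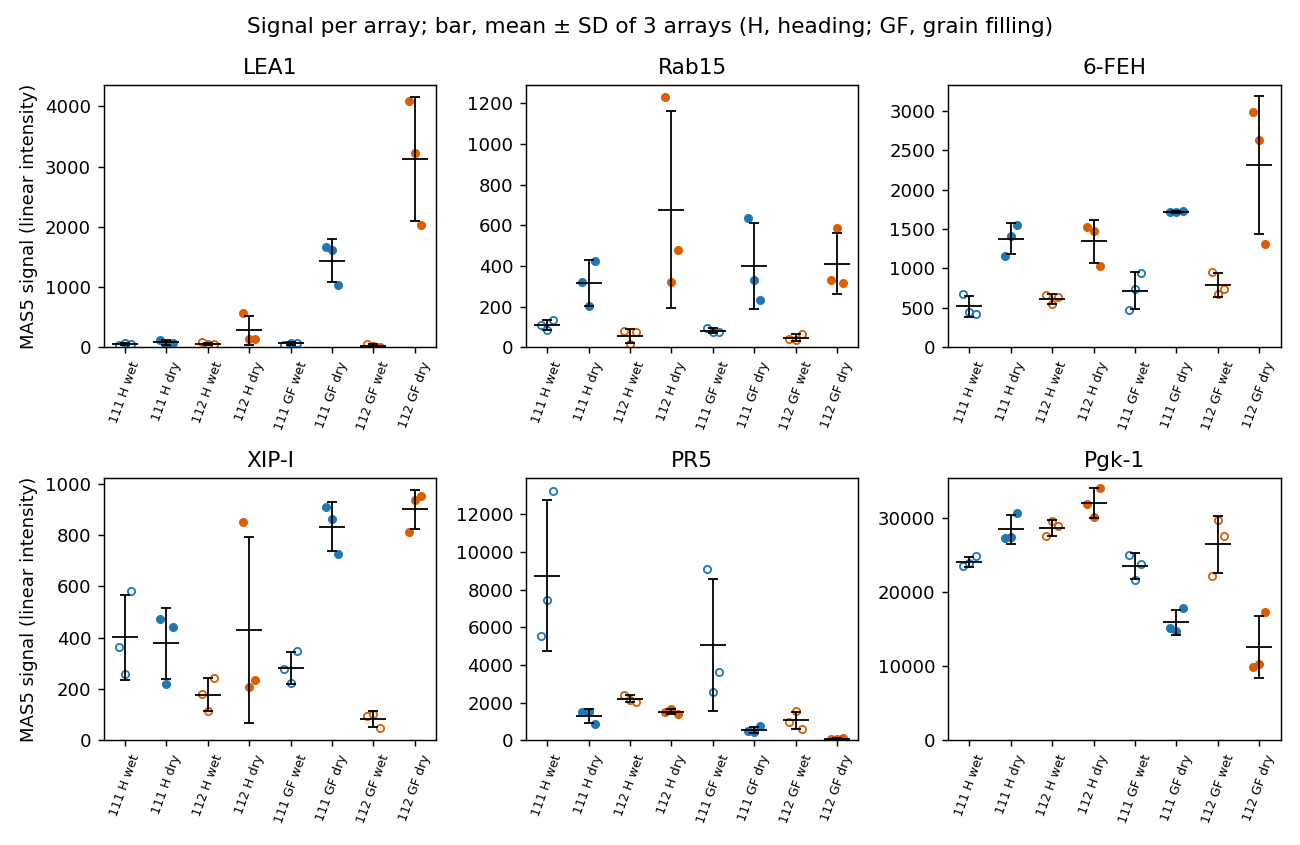
MAS5 signals (y axis, linear scale) of LEA1, Rab15, 6-FEH, XIP-I, PR5 and Pgk-1 in the 8 groups (x axis), with one point per array and the mean ± SD of 3 arrays. LEA1 in dry leaves at grain filling had means of 1438 in TAM 111 and 3117 in TAM 112, against 64.14 and 24.3 in wet leaves.

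The water response of single genes was also compared between stages. In TAM 111, the response of LEA1 was larger at grain filling by 3.96 on the log2 scale (SE 0.675, adjusted p = 0.00312) and that of 1-FEH by 1.04 (SE 0.183, adjusted p = 0.00363). COMT1, lower in dry leaves at heading (9326 ± 2050 to 6037 ± 881) and higher at grain filling (9378 ± 1590 to 13560 ± 55.6; SD, n = 3), differed by 1.16 (adjusted p = 0.00618), RPS29 by -1.44 (0.0127) and PRK by -0.65 (0.015). The brighter RPS29 probe set differed by -0.31 (adjusted p = 0.907). In TAM 112, LEA1 differed by 4.78 (adjusted p = 1.33e-04; 5.32 with a pseudocount of 1 and 4.06 with one 4 times as large, its mean wet signals lying under the filter), GSTZ1 by 1.06 (8.29e-05), tubb3 by -1.39 (2.39e-04), Pgk-1 by -1.27 (4.50e-04) and RPL9 by -1.46 (9.24e-04). PR5, whose fall was called at both stages in TAM 111, differed between stages by -2.78 in TAM 112 (adjusted p = 0.00231) and by -0.28 in TAM 111 (0.87). The test of the difference between stages passed for 1152 probe sets in TAM 111 (659 higher, 493 lower) and 5428 in TAM 112 (2310 and 3118).

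Several of these TAM 111 calls ended with fewer arrays. Without the 3 intermediate arrays 174 probe sets passed and RPS29 (adjusted p = 0.0948), PRK (0.16) and COMT1 (0.0533) did not, and without all 4 arrays numbered 2 of TAM 111 52 passed and LEA1 (0.126) and 1-FEH (0.0562) did not either. PRK also lost its call after quantile normalization (-0.33, adjusted p = 0.241), without the variance trend (0.0503) and without grain filling dry replicate 2 (0.0539). The TAM 111 count was 610, 710, 638 and 743 without heading wet replicate 1, wet replicate 2, dry replicate 2 and dry replicate 3, and 699, 566 and 456 without grain filling wet replicate 1, dry replicate 1 and dry replicate 2. It was 2518 with array weights and 623 without the variance trend. The TAM 112 count was 3520 without grain filling dry replicate 1.

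Between the cultivars, averaged over both water treatments, PR5 was the named gene that differed most at grain filling (at heading -0.81, adjusted p = 0.125). There it was 4.94-fold lower in TAM 112 (log2 difference -2.30, SE 0.283, n = 6 arrays per cultivar, adjusted p = 7.30e-06), and 3 of the 6 TAM 112 arrays lay below all TAM 111 arrays. The histone gene wcH2B-8 was 2.16-fold lower in TAM 112 at grain filling (adjusted p = 8.08e-05). At heading wcH2B-8 was 1.58-fold lower on the same probe set (adjusted p = 0.018). That call was lost without TAM 111 wet replicate 3 (0.0635), TAM 112 wet replicate 1 (0.0534) or TAM 112 dry replicate 1 (0.0522). The wcH2B-8 probe set used for the water and stage effects gave -0.02 at heading (adjusted p = 0.978) and -0.55 at grain filling (adjusted p = 0.0053). The tubulins tubb2 and tubb3 were 1.77-fold (adjusted p = 0.00911) and 1.4-fold (0.00395) lower in TAM 112 at grain filling. For each, 3 of the 6 TAM 112 arrays lay below all TAM 111 arrays. These averages mix wet and dry leaves. The log2 water effect was 0.83 in TAM 111 and -1.07 in TAM 112 for tubb2, and -0.59 and -1.34 for tubb3. The difference between these effects did not pass in limma (adjusted p = 0.0668 and 0.135). Glc1, RPS29, RPL9 and a pair of rbcl probe sets that moved opposite ways also passed at grain filling, by 1.3-fold to 1.75-fold.

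The smaller cultivar differences at grain filling lost their calls with 1 array fewer. The Glc1 call ended without TAM 111 wet replicate 1 (adjusted p = 0.0725), wet replicate 3 (0.0947), dry replicate 2 (0.0789) or dry replicate 3 (0.111), and without TAM 112 wet replicate 1 (0.096), wet replicate 2 (0.0546), dry replicate 1 (0.0843) or dry replicate 2 (0.0734). The RPS29 call ended without TAM 111 wet replicate 1 (0.0502), wet replicate 2 (0.0574), wet replicate 3 (0.051), dry replicate 2 (0.0761) or dry replicate 3 (0.0628), and without TAM 112 wet replicate 2 (0.084) or dry replicate 2 (0.0672). The RPL9 call ended without TAM 111 wet replicate 1 (0.0994), wet replicate 3 (0.0569) or dry replicate 3 (0.096), and without TAM 112 wet replicate 1 (0.102), dry replicate 1 (0.108) or dry replicate 2 (0.0749). The rise of rbcl ended without TAM 111 wet replicate 3 (0.0791) or dry replicate 1 (0.0567), and without TAM 112 wet replicate 1 (0.0679) or dry replicate 1 (0.0713). Its fall ended without TAM 111 wet replicate 3 (0.0594) or dry replicate 1 (0.0512), and without TAM 112 wet replicate 1 (0.0614) or dry replicate 2 (0.071). In all, 1835 probe sets differed at heading (753 higher and 1082 lower in TAM 112) and 4081 at grain filling (1580 and 2501). Probe sets without a named gene differed up to 50.4-fold higher and 301-fold lower in TAM 112 at heading, and up to 76.1-fold higher and 176-fold lower at grain filling.

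From heading to grain filling, averaged over both water treatments, gibberellin oxidases and the histone genes wcH2B-8, H2A-3 and H2A-9 fell. The histone falls were on probe sets taken by the naming rule. On the brightest probe sets, 1 of 5 histone and HMG genes fell in TAM 111 and 2 in TAM 112 (list test adjusted p = 0.447 and 0.608), and wcH2B-8 was not called there in TAM 111 (-0.53, adjusted p = 0.108). On another probe set wcH2B-8 fell 1.93-fold in TAM 111 (log2 change -0.95, SE 0.125, n = 6 arrays per stage, adjusted p = 2.07e-05) and 2.8-fold in TAM 112 (adjusted p = 5.21e-08). H2A-3 fell 2.19-fold in TAM 111 (limma adjusted p = 8.44e-04) and 1.85-fold in TAM 112 (0.00286). H2A-9 fell 2.81-fold in TAM 111 (0.00539) and, on a different probe set, 2.24-fold in TAM 112 (1.74e-04). The 3 gibberellin oxidases fell in TAM 111 and 2 of them in TAM 112 (1 with a pseudocount of 1), with GA20ox1a 3.44-fold lower in TAM 111 (adjusted p = 0.00897, and 0.0899 without the 3 intermediate arrays). The lipid transfer gene LTP3 fell 1.74-fold (adjusted p = 1.08e-04) and the peptidyl-prolyl isomerase FKBP70 1.63-fold (8.25e-05) in TAM 111. In TAM 112 PR5 fell 5.77-fold (adjusted p = 1.36e-06), the tubulin Tubb5 1.9-fold (3.67e-05) and PEAMT1, an enzyme of choline synthesis, 1.84-fold (0.00495). PR5 means there went from 2206 to 1062 in wet leaves and from 1520 to 96.37 in dry leaves. The average of LEA1 over water was 4.38-fold higher at grain filling in TAM 111 (adjusted p = 1.59e-04) and 2.46-fold higher in TAM 112 (0.00543). The wet means went from 55.46 to 64.14 and from 58.46 to 24.3, and the dry means from 78.57 to 1438 and from 279 to 3117. PIMT rose 1.78-fold (7.51e-04) and 1.56-fold (0.00279), and 3 of 6 grain filling arrays in each cultivar lay above all heading arrays. Its log2 water effect was 0.27 at heading and 1.41 at grain filling in TAM 111, and 0.08 and 1.49 in TAM 112. The averaged rise of PIMT thus includes the larger response of dry leaves at grain filling. In TAM 111 a rbcl probe set, WZF1, tubb1, COMT1, Glc1 and RPS29 were also called higher, by 1.37-fold to 2.49-fold. PR5 and PEAMT1 were called lower there, by 2.05-fold and 1.68-fold. In TAM 112 WZF1, 6-FEH, Glc1 and 1-FEH were called higher, by 1.6-fold to 2.01-fold. Another rbcl probe set and a PsbP probe set were called lower in TAM 112, by 1.93-fold and 1.77-fold. Photosynthesis genes were lower for 1 of 7 in TAM 111 (0 after quantile normalization) and 5 of 7 in TAM 112 (list test adjusted p = 0.29 in each). Of 6 tubulins, 4 fell in TAM 112 and 1 rose in TAM 111 (1 rose and 1 fell after quantile normalization).

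In total 6253 probe sets changed with stage in TAM 111 (3025 higher, 3228 lower) and 11036 in TAM 112 (4924 and 6112). Without the 3 intermediate arrays the TAM 111 count was 3690, and without the 4 arrays numbered 2 it was 2567. The TAM 111 stage calls of tubb1 (adjusted p = 0.113), WZF1 (0.11), PR5 (0.12), Glc1 (0.0848) and H2A-9 (0.0504) ended without the 3 intermediate arrays. All 6 arrays of one stage lay beyond all 6 of the other for 5 of 16 named genes in TAM 111 and 5 of 14 in TAM 112.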

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

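Of the tests in this part, the splits with additive effects removed and the size of the response in TAM 112 were chosen only after the result was seen.

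The difference of the water response between cultivars passed for 1 probe set at heading and 13 at grain filling, and the difference between stages for 1152 in TAM 111 and 5428 in TAM 112; each is listed because a test of the difference itself passed. The gene at heading was GA20ox1d (-3.71, but 1.55 with adjusted p = 0.978 on a second probe set). Between stages in TAM 111 the genes were LEA1 (3.96), 1-FEH (1.04), COMT1 (1.16), RPS29 (-1.44, but -0.31 with adjusted p = 0.907 on its brighter probe set) and PRK (-0.65), and in TAM 112 they were GSTZ1 (1.06), LEA1 (4.78), tubb3 (-1.39), Pgk-1 (-1.27) and RPL9 (-1.46).

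Sucrose synthase, which splits sucrose for use in the cell, gave a signal outside the main tests, since its probe sets are controls on this array. The 3' probe set went from 3264 ± 522 to 4430 ± 539 in dry TAM 111 leaves at grain filling (SD, n = 3; log2 change 0.44, limma adjusted p = 0.0315) and from 3426 ± 542 to 6401 ± 566 in TAM 112 (0.91, adjusted p = 3.81e-05). The middle probe set rose in TAM 112 (0.72, adjusted p = 0.0059). The 5' probe set, near background, was not called (TAM 111 0.22, adjusted p = 0.74; TAM 112 0.01, adjusted p = 0.981). In the same comparisons the log2 ratio of the 3' to the 5' GAPDH probe set went from -2.43 ± 0.478 to -1.7 ± 0.735 in TAM 111 and from -2.73 ± 1.25 to -1.06 ± 0.489 in TAM 112 (SD, n = 3). That ratio was negative on every array, so it is a limited sign of RNA quality. The difference between cultivars was 0.46 for the 3' sucrose synthase probe set (adjusted p = 0.301).

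Splits of the arrays were compared with the real grouping. For each water effect there are only 10 splits, which are too few. Of the 10, 1, the real grouping, gave as many calls. There were 1705 and 7096 in TAM 111 at heading and grain filling (highest other 1 and 7) and 1351 and 11869 in TAM 112 (1 and 2030). For the cultivar effects, 1 of 100 splits, the real one, gave as many calls as the 1835 at heading (highest other 638) and 4081 at grain filling (3802). The same held for the 6253 and 11036 stage calls in TAM 111 (highest other 3440) and TAM 112 (9332). A chance labelling of these arrays was thus argued against. The replicates may not be separate plants, so these splits cannot exclude chance differences between plants. For the differences of the water response, 12 (highest 782) and 17 (highest 4081) of 100 splits gave as many calls between cultivars at heading and grain filling, and 7 (highest 6253) and 9 (highest 11036) between stages in TAM 111 and TAM 112. Chance was not excluded by these splits, some of which turn the difference into the cultivar or stage effect itself, a structure of the samples. With the additive effects removed first, 1 (highest other 0), 4 (highest 241), 1 (highest 118) and 1 (highest 3868) of 100 did, in the same order. These later splits, chosen after the result was seen, argued against a chance labelling of these arrays for the stage differences only. The cultivar differences stay open, since their 1 and 13 calls ran from 0 to 2 and from 2 to 2438 on leaving out 1 array.

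The larger number of calls in TAM 112 at grain filling was weighed against technical causes. A smaller spread between TAM 112 arrays was not seen, since their residual SD was 1.19 times that of TAM 111 (0.311 against 0.261). The fit gave each probe set 1 variance for all 8 groups, so a smaller spread could not have raised the TAM 112 number alone. With only its own 6 arrays in the fit, the TAM 112 number was 7794 against 11869. Whether the shared variance raised that number was left open. Whether the intermediate wet array of TAM 111 lowered the TAM 111 number stays open too. That number was 5527 without the array, but leaving out any 1 of the 6 arrays lowered it (5159 to 6249 against 7096), so this test decides nothing. A larger response of the same genes, the biological explanation, was left open. The principal-axis slope of TAM 112 against TAM 111 log2 changes was 1.21. Scores of array pairs of one replicate number were 0.964, 0.944 and 0.826 in TAM 111 and 1.17, 1.13 and 0.962 in TAM 112 (exact permutation p = 0.2, the smallest possible being 0.1). The arrays of a pair share only that number, and pair 2 of TAM 111 holds the intermediate wet array.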

How the results depend on the processing

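None of the named gene results followed here changed direction, while list tests were followed by their p alone. Of 1828 alternative values for 94 named gene results, 1673 kept their call, 155 lost it and 0 reversed. Signal over background limits dim probe sets most, and the cause of the changes below was not tested except where fewer arrays were used. With array weights, calls were 2595 for water in TAM 111 at heading, 1552 for cultivar by water at grain filling and 2518 for stage by water in TAM 111. With only the arrays compared they were 7794 for water in TAM 112 at grain filling, and 0 and 4 for cultivar by water at heading and grain filling. Cultivar by water at heading gave 0 with a pseudocount of 1 or the stricter filter and 2 with the larger pseudocount, and at grain filling 37 with the larger pseudocount and 23 after quantile normalization. Without the variance trend the numbers were 8 for cultivar by water at grain filling and 623 for stage by water in TAM 111.

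Without the 3 intermediate arrays, chosen after seeing the data, calls were 857 for water in TAM 111 at heading, 0 and 24 for cultivar by water at heading and grain filling, 174 for stage by water and 3690 for stage in TAM 111, 443 shared at heading and 0 lists. Without the 4 arrays numbered 2 of TAM 111, also chosen afterwards, they were 758 and 3867 for water in TAM 111, 0 and 20 for cultivar by water, 52 for stage by water and 2567 for stage in TAM 111, 413 and 3211 shared, and 0 lists. The photosynthesis list at grain filling gave adjusted p = 0.693 and 0.361 in TAM 111 and TAM 112 after quantile normalization, 0.477 in both with an estimated correlation (0 lists), 0.135 and 0.0704 without the 3 arrays and 0.119 and 0.0872 without the 4.

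Leaving out 1 array at a time gave 796 to 1530 calls for water in TAM 111 at heading, 5159 to 6249 at grain filling, 479 to 1176 in TAM 112 at heading and 9255 to 12535 at grain filling. It gave 0 to 2 and 2 to 2438 for cultivar by water at heading and grain filling, 456 to 1403 and 3520 to 7419 for stage by water in TAM 111 and TAM 112, 1414 to 1922 and 2921 to 6049 for cultivar at heading and grain filling, 4526 to 6434 and 9242 to 12065 for stage in TAM 111 and TAM 112, and 345 to 640 and 4134 to 5182 shared at heading and grain filling.

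By the labels, replicates of different groups share only a number. The deviations of arrays from their group means were therefore correlated, rather than the signals themselves. For wet and dry arrays of one number these correlations were -0.0479 to 0.183 in 12 pairs, 2 of them above 0.1. By this measure 11 of 24 arrays correlated best with their own number, so the arrays were not paired. With the number as a block, cultivar by water gave 0 at heading and 167 at grain filling.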

Other observations

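Of the tests in this part, only that of a swapped sample was chosen after the result was seen.

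The intermediate TAM 111 arrays (replicate 2 at heading, wet and dry, and at grain filling, wet) were placed on a linear scale from 0 at TAM 112 to 1 at TAM 111, using 157 probe sets with a large cultivar difference (88 bright in TAM 111, 69 bright in TAM 112). By their median over the 3 arrays, 95.5% of these probe sets lay between 0.2 and 0.8 (92.4%, 87.9% and 91.7% on the single arrays), which is consistent with material of both cultivars in these samples. A swapped sample was argued against by the median position of 0.495, and poor array or RNA quality by the highest of the 3 medians over probe sets bright in TAM 112, 0.514, since lost signal would not raise them. The medians per array were 0.491, 0.465 and 0.514, and replicate 2 at grain filling, dry, lay at 0.991. No test separated a mixture of RNA or leaves from a plant descended from both cultivars.

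A hypothesis on the cultivar effect was that TAM 112 carries a rye arm in place of the short arm of wheat chromosome 1A, as some wheat cultivars do, so that wheat probe sets of that arm would read lower. Of 23 probe sets assigned to the short-arm side of 1A in the IWGSC CS RefSeq v2.1 assembly, 6 (26.1%) were lower in TAM 112 at both stages, against 14 of 942 (1.49%) elsewhere (Fisher exact p = 2.86e-06). Counted by gene it was 6 of 14 against 14 of 626 (Fisher exact p = 1.07e-06), and on the long-arm side 2 of 38 probe sets (Fisher exact p = 0.184). The result is consistent with such an arm, and sequence variants between the cultivars in the same region could give it too, which was not tested.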
